A study of Homo sapiens with 6 samples.

How the data were processed

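RNA from 6 samples of MDA-MB-231, an established human triple-negative breast cancer cell line, was sequenced as 6 libraries. Per the labels' protocols, 3 samples were transfected with an empty vector (control) and 3 with a plasmid carrying ABI2, RNA was isolated with a Trizol reagent, and libraries were made with an mRNA kit. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

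The authors deposited 1 table with a row per gene. Per the file headers, each library had a deposited read count, a TPM value (transcripts per 1e6 transcripts) and an FPKM value (fragments per kilobase and 1e6 fragments). The deposited counts were whole numbers with no normalization. The deposited TPM values summed to between 999953 and 999992 per library, and the deposited FPKM values were proportional to TPM within a library. Per the submitters' processing notes, FastQC 0.11.2, Trimmomatic, HISAT2 2.1.0, StringTie 1.3.3b and the GRCh38 build were used. The order of these steps, the gene annotation, the counting program and its strand setting are not given in the sources used here. Without a strand setting, reads of overlapping genes and of antisense partners cannot be told apart.

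The table held 20260 complete rows. 1 further row, the last, broke off within a value and was left out. The rows included 19719 of the 19951 protein-coding genes of GENCODE release 29, and 4076 genes had no count in any library. Library totals, in units of 1e6 counts, were 38.45 to 40.31. Libraries of one group differed from each other by more than counting noise, with a chi-square per degree of freedom of 21.18 to 48.46, so none was a copy of another.

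Counts were compared with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with its default minimum count of 10, dispersions and quasi-likelihood fits with robust settings, and the two-sided quasi-likelihood F test of ABI2 plasmid against control. Genes with a Benjamini-Hochberg adjusted p below 0.05 were counted as changed. The filter left 13325 genes. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. Levels are given as CPM, counts per 1e6 counts of the TMM-scaled library. Single values per library were compared by an exact two-sided permutation test over the 6 libraries, which cannot give a p below 0.1.

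28 gene lists were fixed before the data were examined, and 27 of them had at least 5 tested members. These were tested with limma 3.58.1: camera with a preset inter-gene correlation of 0.01, camera with a correlation estimated per list, and fry, each adjusted over the lists. Members were counted as rising or falling by the edgeR test over all genes, and a second time with p-values adjusted over the list alone.

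Named genes followed a rule also fixed before the data were examined. It took the ABI family; the 10 genes with the largest rise and the 10 with the largest fall among symbol-named genes whose groups did not overlap and whose higher group had at least 1 CPM; the 5 with the smallest p in each direction; and up to 4 members of each list with the smallest p. Genes outside the rule are said to have been chosen after their values were seen. Some genes that the rule takes, and 1 of the lists, are not reported here. Of the 146 named genes, 32 overlapped another gene of the table, 13 of them on the same strand.

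Transcript GC content and length came from GENCODE release 29, from the transcript with the longest coding sequence of each gene. 20221 of the table's genes matched by identifier, and 13314 of the tested genes had a GC value. Coordinates are those of the table, on GRCh38. They equalled those of GENCODE release 29 for 80.6% of the matched rows. After the fold changes were seen to follow GC content, a GC-corrected fit was added. In it, each library's log2 CPM deviations from the gene means were fitted with a natural spline of GC with 5 degrees of freedom, over genes with a mean log2 CPM above 0, and the fitted values entered the edgeR fit as offsets. Such a correction also removes any real change that goes with GC content.

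The procedure was tested on simulated counts for this comparison, drawn from the real means, library sizes and dispersions. Without a GC trend, 13210 genes were tested, and the planned fit recovered 46.3% of the genes changed 1.5-fold, 86.6% of those changed 2-fold and 100% of those changed 4-fold. It called 0.116% of the unchanged genes. With a simulated GC trend between the groups, 13092 genes were tested, and the planned fit called 72.9% of the unchanged genes. With the GC correction, 13077 genes were tested, 35.8%, 82.1% and 93.9% of the genes changed 1.5-fold, 2-fold and 4-fold were recovered, and 0.125% of the unchanged genes were called. The simulated trend was a smooth function of the same GC values that the correction fits, and few genes were changed. In the real data the GC-corrected fit called 51.2% of the genes, so these rates need not hold there.

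The settings fixed before the data were seen were RLE scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter at 1 CPM, the replicate number as a block, leaving out each library in turn, and a minimum absolute log2 fold change of 1. Added after seeing the data were the GC correction, a correction for GC and length, library size without TMM, and limma on log2(TPM + 1) for genes of at least 1 TPM in at least 3 libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Floors for genes without counts take 3 counts over the 3 libraries of a group. These floors, and the 95% Clopper-Pearson interval given for 1 ratio, cover counting error only, since reads without molecular identifiers are not independent molecules.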

Results

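The transcriptome of MDA-MB-231 cells was measured with and without overexpression of ABI2, an adaptor protein of the WAVE complex that drives branched actin assembly. MDA-MB-231 is a mesenchymal-like, triple-negative breast cancer line. The series asks what ABI2 does in these cells, with PI3K/AKT signalling named in its title. There were 3 control libraries from cells given an empty vector and 3 libraries from cells given the ABI2 plasmid. Total counts, in units of 1e6, were 39.6 ± 0.99 in the control libraries and 39.6 ± 0.53 in the ABI2 libraries (mean ± SD, n = 3 each).

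ABI2 was higher in every library that received the ABI2 plasmid. ABI2 (ENSG00000138443, chromosome 2, 203328219 to 203447723, plus strand, GRCh38) had 3374 ± 99.8 counts in the control libraries and 8512 ± 104 counts in the ABI2 libraries (SD, n = 3 each). On the scaled level this was 82.5 ± 1.2 CPM against 222 ± 2.27 CPM, a 2.69-fold difference. The log2 fold change was 1.43 ± 0.04 (SE; edgeR quasi-likelihood test, adjusted p = 1.23e-05). The exact permutation test of the 6 CPM values gave p = 0.1, the smallest it can give. The GC-corrected fit gave ABI2 a log2 fold change of 2.78. That fit used the GC content of the annotated transcript, 41.66% over 22209 bp, of which 20374 bp are 3' untranslated region. If the added reads came from a plasmid transcript without that region, which stays open, this GC content would not apply to them. ABI1, the close relative of ABI2 in the WAVE complex, was at 119 ± 4.18 CPM in control and 87.9 ± 5.15 CPM in ABI2 libraries, a log2 fold change of -0.44 ± 0.06 (edgeR adjusted p = 0.000514) that became 1.26 in the GC-corrected fit.

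**Figure D1:**
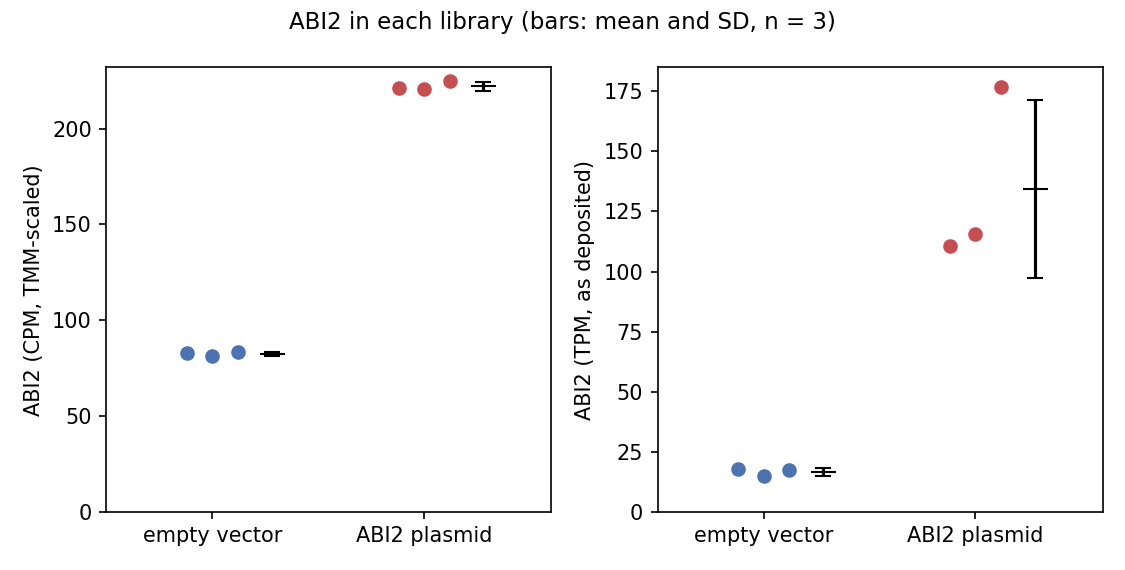
ABI2 in each of the 6 libraries, as TMM-scaled CPM (left axis) and as the deposited TPM (right panel). Points are libraries and black bars are the mean and SD of 3 libraries. The CPM of the ABI2 libraries lay between 220.5 and 224.72, against 81.1 to 83.35 in control, while their TPM ranged from 110.734 to 176.792.

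Expression differed between the groups across most of the transcriptome, with larger falls than rises. Of 13325 genes tested, 4680 were higher and 5057 were lower in the ABI2 libraries, 73.1% in all. Rises and falls are relative to the TMM scaling, which takes most genes as unchanged, so their balance depends on it. With library size without TMM, 4101 were higher and 5420 lower. At least a 2-fold change was seen in 247 of the genes that rose and in 3322 of those that fell, and at least a 4-fold change in 15 and 1366. The median log2 fold change was 0.61 among genes that rose and -1.38 among those that fell. Values of the 2 groups did not overlap for 10381 genes, 77.9% of those tested, where chance gives 10%.

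The changes followed the GC content of the transcripts. In the tenth of genes with the lowest GC content (31.8% to 39.1%), 1233 of 1332 genes fell and 7 rose, with a median log2 fold change of -1.84. In the tenth with the highest GC content (62.6% to 74.7%), 984 of 1332 rose and 12 fell, with a median of 0.63. Across genes, which are not independent replicates, Spearman's rho between fold change and GC content was 0.79 and Pearson's r was 0.733. The count-weighted GC content was 51.1% ± 0.26 in control and 53.9% ± 0.22 in ABI2 libraries (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). With the GC correction, chosen after this trend was seen, 3811 genes rose and 3009 fell. Of the changes called in the planned fit, 4301 kept their call and direction there and 1209 were called in the opposite direction.

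**Figure D2:**
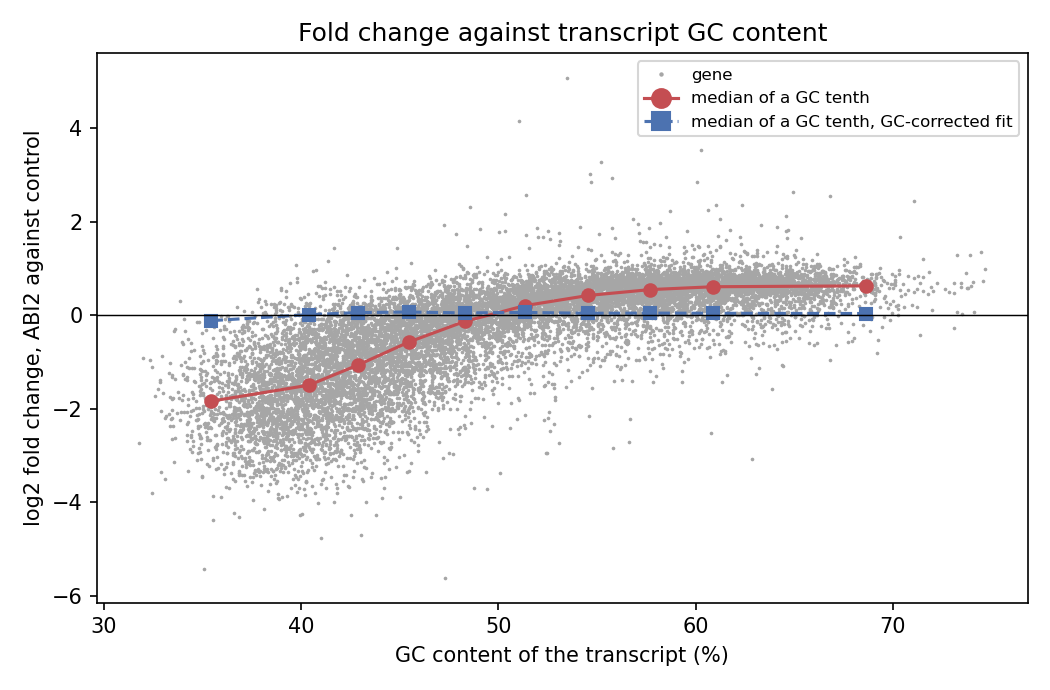
Log2 fold change of ABI2 against control libraries for each tested gene, by the GC content of its transcript in percent. Circles are medians of GC bins of equal size in the planned fit, from -1.84 at the lowest to 0.63 at the highest GC content, and squares are the medians in the GC-corrected fit, from -0.11 to 0.04. 7 genes with a log2 fold change beyond 6 in size are not drawn.

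The genes with the largest rises included a keratin, a mucin and ID1. ID3 and B4GALT5, also given here, were taken as rises with the smallest p. KRT17 (ENSG00000128422, chromosome 17, 41619437 to 41624842), a basal keratin, had 2 counts in the control libraries together and 145 in the ABI2 libraries, a ratio of 77.4 with a 95% Clopper-Pearson interval of 21 to 645. Both control counts were in control replicate 1, so the ratio rests on that library, and without it the log2 fold change of KRT17 went from 6.03 to 8.64. MUC5AC (ENSG00000215182, chromosome 11, 1157953 to 1201138), a secreted gel-forming mucin, went from 0.25 ± 0.1 to 2.97 ± 0.94 CPM (SD, n = 3 each). ID1 (ENSG00000125968, chromosome 20, 31605283 to 31606515), an inhibitor of basic helix-loop-helix factors, rose from 93.8 ± 1.44 to 343 ± 9.27 CPM, and its relative ID3 rose from 19.8 ± 0.81 to 66.8 ± 0.57 CPM. Both kept log2 fold changes above 1 in the GC-corrected fit, 1.36 ± 0.03 for ID1 and 1.26 ± 0.05 for ID3 (SE). ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose from 3.74 ± 0.26 to 14.3 ± 1.52 CPM, and B4GALT5, a galactosyltransferase, from 183 ± 2.4 to 390 ± 3.47 CPM. KRT17, MUC5AC, ANGPTL4 and B4GALT5 had log2 fold changes of 6.03, 3.54, 1.93 and 1.09 in the planned fit. In the GC-corrected fit they had 5.49, 2.98, 1.34 and 1.325. PRR5L, a component of mTORC2, had log2 fold changes of 1.85 and 1.93 in the planned and GC-corrected fits, and CRYM, a thyroid hormone binding protein, had 1.87 and 1.67. The ABI2 libraries differed for PRR5L, with 575, 576 and 236 counts (12.04 ± 5.05 CPM, SD, n = 3). Its log2 fold change was 2.16 without ABI2 replicate 3. In the TPM fit it was 0.94, but there the 1 added to each TPM value shrinks fold changes of genes at low levels. BCL2L2-PABPN1, a read-through gene, had 1.95 and 1.46, and its reads cannot be separated from those of BCL2L2 and PABPN1.

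SH3BP1, a GTPase activating protein, was also among the 10 largest rises, at 75.4 ± 61.6 CPM in ABI2 against 20.5 ± 2.21 CPM in control libraries. It had 5568 counts in ABI2 replicate 3 and 1528 and 1541 in the others, while the overlapping gene PDXP had 977 counts in that library against 4447 and 4728. Without ABI2 replicate 3 the log2 fold change of SH3BP1 was 0.96, and in the GC-corrected fit, at 1.27, it no longer passed (edgeR adjusted p = 0.103). SH3BP1 also lost its call with limma-voom, at 1.59, and with the GC and length correction, at 1.29. The same was seen without control replicate 1, 2 or 3, at 1.94, 1.80 and 1.92.

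Of the 10 genes with the largest falls, 9 had a GC value, from 36.83% to 43.27%. KLRK1 (ENSG00000213809, chromosome 12, 10372353 to 10391874), a natural killer cell receptor, had 347 counts in the control libraries together and none in the ABI2 libraries, at least 108-fold lower with a floor of 3 counts over the group. The overlapping read-through gene KLRC4-KLRK1 had 19 to 36 counts per control library and 17 to 23 per ABI2 library, so the assignment of reads to KLRK1 is uncertain. PJA2, a ubiquitin ligase, fell from 112 ± 25.6 to 6.33 ± 0.86 CPM, BTAF1, a regulator of TATA-binding protein, from 46.3 ± 6.07 to 2.85 ± 0.42 CPM, and DENND4C from 11.2 ± 2.03 to 0.58 ± 0.12 CPM (SD, n = 3 each). LEPR, C5, CRYBG3, HEATR5B and DOPEY1 had log2 fold changes of -4.32, -4.28, -4.25, -3.99 and -3.99, and FAM106A had -4.05. Reads of LEPR are shared with the overlapping gene LEPROT. After GC correction the log2 fold changes of PJA2, BTAF1 and DENND4C were -2.43, -2.57 and -3.07, those of LEPR, C5, CRYBG3, HEATR5B and DOPEY1 were -2.56, -2.73, -2.71, -2.94 and -2.66, and FAM106A had no GC value. Among the falls with the smallest p were RB1, the retinoblastoma tumour suppressor, from 55.4 ± 0.78 to 12.9 ± 0.42 CPM, and the phosphodiesterase PDE4D, from 20.9 ± 0.64 to 2.54 ± 0.06 CPM. MBNL1, PREPL and ARHGAP12 were the others, with log2 fold changes of -2.43, -3.47 and -2.46. The log2 fold change of RB1 was -2.10 ± 0.07 in the planned fit and -0.34 in the GC-corrected fit, where PDE4D, MBNL1, PREPL and ARHGAP12 had -1.52, -0.87, -1.71 and -0.84.

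PI3K/AKT pathway components changed in both directions. Of 34 measured members, whose median GC content was 51.3%, 11 rose, 14 fell and 9 did not pass. PIK3CA, the p110-alpha catalytic subunit, fell from 20.3 ± 2.11 to 2.84 ± 0.08 CPM and PIK3C2A, a class II PI3-kinase, from 13.5 ± 1.29 to 1.26 ± 0.12 CPM. RPTOR, the scaffold of mTORC1, rose from 119 ± 3.79 to 196 ± 2.51 CPM. Among members chosen after their values were seen, AKT1 rose from 147 ± 7.36 to 245 ± 12.2 CPM and AKT2 from 98.9 ± 4.15 to 144 ± 2.58 CPM. After GC correction the log2 fold changes were -0.99 for PIK3CA, -1.66 for PIK3C2A, 0.17 for RPTOR and 0.20 for AKT1, that of AKT2 was 0.02 and no longer passed (edgeR adjusted p = 0.755), and 8 members rose and 13 fell. Camera did not separate the list from other genes (adjusted p = 0.713 in the planned fit and 0.126 in the GC-corrected fit).

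FOXO targets, which FOXO factors induce when AKT activity is low, did not rise together. Of 19 measured members, with a median GC content of 45.9%, 1 rose, 10 fell and 8 did not pass (camera adjusted p = 0.325, and 0.841 in the GC-corrected fit). Of all genes in the tenth from 44.1% to 46.8% GC content, 62% fell and 8% rose. The list lay near these shares, so its counts do not speak to AKT activity. SESN3, a stress-induced inhibitor of mTORC1, fell from 8.73 ± 1.44 to 0.75 ± 0.16 CPM and RBL2, a pocket protein, from 79.9 ± 4.51 to 20.3 ± 3.59 CPM. The member that rose was CITED2, a transcriptional coregulator, from 116 ± 2.62 to 169 ± 14.1 CPM. CCNG2, cyclin G2, had a log2 fold change of -0.64 ± 0.07 in the planned fit and 0.81 in the GC-corrected fit, where SESN3, RBL2 and CITED2 had -1.77, -0.89 and 0.55, and 5 members rose and 7 fell.

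The partners of ABI2 in actin regulation changed in both directions. In the list of the WAVE complex and ABI partners, 6 of 16 measured members rose, 6 fell and 4 did not pass (median GC content 47.4%, camera adjusted p = 0.763). The rises included SH3BP1, whose uneven counts between the ABI2 libraries and lost calls are given above. NCKAP1, a core subunit of the WAVE complex, fell from 175 ± 33.6 to 32.9 ± 2.42 CPM, EPS8 from 23.9 ± 1.08 to 6.84 ± 0.76 CPM, and SOS1 from 14.6 ± 0.52 to 3.33 ± 0.88 CPM, and BAIAP2 rose from 67.8 ± 2.72 to 115 ± 2.31 CPM. Adjusted over the list alone, 6 rose and 7 fell. After GC correction the log2 fold changes were -1.30 for NCKAP1, -0.62 for EPS8 and 0.18 for BAIAP2, and SOS1, at -0.41, no longer passed (edgeR adjusted p = 0.0779), and 6 members rose and 5 fell.

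In the Arp2/3 and actin cytoskeleton list, 12 of 25 rose, 9 fell and 4 did not pass, and 11 rose and 5 fell after GC correction (median GC content 50.9%, camera adjusted p = 0.55). The Arp2/3 subunits ARPC1B and ARPC4 and the actin-severing protein cofilin, CFL1, had log2 fold changes of 0.69, 0.69 and 0.68, and the formin DIAPH3 had -1.97, against 0.17, 0.36, 0.16 and -0.49 after GC correction. Targets of SRF and MRTF, the transcription factors that respond to actin assembly, gave 13 rises and 7 falls among 24, with 4 not passed, and 7 rises and 7 falls after GC correction (median GC content 56%, camera adjusted p = 0.296). SRF itself rose from 147 ± 4.46 to 254 ± 6.96 CPM, beta-actin, ACTB, from 2723 ± 93.9 to 4274 ± 69.5 CPM, PDLIM7 from 197 ± 10.8 to 380.1 ± 4.77 CPM, and filamin A, FLNA, from 1309 ± 42.3 to 2097 ± 51.7 CPM. Their log2 fold changes after GC correction were 0.22, 0.20, 0.35 and 0.09. YAP/TEAD targets gave 11 rises and 10 falls among 24, with 3 not passed, and 9 rises and 4 falls after GC correction (median GC content 50.9%, camera adjusted p = 0.445). CYR61, a secreted matricellular protein, had log2 fold changes of 0.82 and 0.77 in the planned and GC-corrected fits, FJX1 had 1.07 and 0.47, and the receptor AXL had 0.69 and 0.34.

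Most members of the mitosis list fell and genes of DNA replication moved both ways. In the G2/M and mitosis list 25 of 36 measured members fell, 8 rose and 3 did not pass, with a median log2 fold change of -1.18 (camera adjusted p = 0.0211, and adjusted p = 0.633 with an estimated correlation). TOP2A, topoisomerase II alpha, fell from 94.3 ± 16.3 to 12.9 ± 0.8 CPM, MKI67, the proliferation marker Ki-67, from 139 ± 8.67 to 50.5 ± 2.96 CPM, and the mitotic kinesins KIF11 and KIF23 from 35.8 ± 3.01 to 7.36 ± 0.41 CPM and from 34.8 ± 3.02 to 6.41 ± 0.67 CPM. The members' median GC content was 44.7%, and in the tenth of all genes from 44.1% to 46.8% GC content, 62% fell and 8% rose. With the GC correction 16 members of the list fell and 4 rose, their median was -0.15 and the camera adjusted p was 0.0771. The log2 fold changes there were -1.23 for TOP2A, -1.27 for MKI67, -0.58 for KIF11 and -1.19 for KIF23. Of 38 genes of G1/S and DNA replication, 17 rose, 15 fell and 6 did not pass (median GC content 48.9%, camera adjusted p = 0.713), and adjusted over the list alone 17 rose and 16 fell. The GC-corrected fit had 19 rises and 9 falls. The helicase subunits MCM5 and MCM7 and the licensing factor CDT1 had log2 fold changes of 0.88, 0.75 and 0.96 in the planned fit and 0.41, 0.24 and 0.36 in the GC-corrected fit, and MCM10 had -1.98 and -1.62.

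CDKN1A, the cell cycle inhibitor p21, rose from 106 ± 3.54 to 208 ± 10.3 CPM, the pro-apoptotic gene BAX from 180.1 ± 6.94 to 308 ± 6.35 CPM and the exonuclease AEN from 33.1 ± 2.39 to 72.6 ± 4.37 CPM, while ZMAT3 fell from 27.7 ± 1.56 to 6.65 ± 1.03 CPM. In the planned fit their log2 fold changes were 0.97, 0.77, 1.13 and -2.06, and after GC correction 0.46, 0.24, 0.69 and -0.46. Apoptosis regulators gave 8 rises, 7 falls and 11 not passed among 26, and 13 rises and 4 falls after GC correction (median GC content 45.8%, camera adjusted p = 0.713). The caspase inhibitors XIAP and BIRC3 had log2 fold changes of -1.89 and -2.95, and -0.24 and -1.10 in the GC-corrected fit, while the pro-apoptotic gene BOK had 0.97 and 0.37.

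Most measured NF-kB targets and cytokines rose. In the list of NF-kB targets and cytokines, 17 of 27 members rose, 5 fell and 5 did not pass, with a median log2 fold change of 0.45 (median GC content 50.3%, camera adjusted p = 0.0283, and adjusted p = 0.633 with an estimated correlation). The colony-stimulating factor CSF3 rose from 141 ± 5.66 to 312 ± 17.3 CPM and CSF2 from 3.34 ± 0.38 to 11.7 ± 0.26 CPM, the neutrophil chemokine CXCL1 rose from 23.5 ± 0.55 to 51.1 ± 2.64 CPM, and BIRC3 fell from 7.79 ± 0.78 to 1.01 ± 0.19 CPM. In the GC-corrected fit 19 rose and 5 fell, with a median of 0.49 and a camera adjusted p of 0.00846 (adjusted p = 0.547 with an estimated correlation, and 0.00998 with the GC and length correction). The log2 fold changes there were 0.60 for CSF3, 1.75 for CSF2 and 1.77 for CXCL1. In the list of ERK output, 14 of 22 rose, 1 fell and 7 did not pass (median GC content 55.2%, camera adjusted p = 0.00772, and adjusted p = 0.633 with an estimated correlation). The receptor EPHA2, the phosphatase DUSP1 and the transcription factors ETV4 and JUNB had log2 fold changes of 0.72, 0.75, 0.78 and 0.81, and in the GC-corrected fit of 0.16, 0.34, 0.21 and 0.21. There 14 rose and 3 fell with a camera adjusted p of 0.13. In the planned fit, 59.8% of all genes in the tenth from 52.9% to 56.2% GC content rose and 6.1% fell. In the tenth that holds the median of the NF-kB list (49.8% to 52.9%), 43.1% rose and 13.8% fell.

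Interferon-stimulated genes split. Of 36 measured members, 11 rose, 16 fell and 9 did not pass (median GC content 45.3%, camera adjusted p = 0.803), and in the GC-corrected fit 9 rose and 9 fell. In the tenth of all genes from 44.1% to 46.8% GC content, 62% fell and 8% rose. ISG15 (ENSG00000187608, chromosome 1, 1001138 to 1014541), a ubiquitin-like modifier, rose from 202 ± 9.6 to 719 ± 23.9 CPM and the exonuclease ISG20 from 20.2 ± 1.31 to 74.7 ± 2.7 CPM. Both were also among the 10 largest rises. The RNA sensor DDX58, now called RIGI, fell from 73.6 ± 15.5 to 8.61 ± 0.71 CPM and IFIT5 from 20.6 ± 2.53 to 3.95 ± 0.53 CPM. Their log2 fold changes in the GC-corrected fit were 1.24, 1.53, -1.59 and -0.62.

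Most members of the hypoxia and glycolysis list rose, and stress and lipid genes went both ways. In this list, 20 of 29 members rose, 7 fell and 2 did not pass (median GC content 55%, camera adjusted p = 0.0283, and adjusted p = 0.633 with an estimated correlation). Of all genes in the tenth from 52.9% to 56.2% GC content, 59.8% rose and 6.1% fell. PFKP, a phosphofructokinase, rose from 540.1 ± 16 to 908 ± 27.9 CPM and the glucose transporter SLC2A1 from 209.9 ± 6.85 to 370.02 ± 13.1 CPM, while the histone demethylase KDM3A fell from 104 ± 6.81 to 15.3 ± 3.61 CPM. BNIP3L, a mitophagy receptor, had a log2 fold change of -1.37 ± 0.08 in the planned and 0.28 in the GC-corrected fit, where 19 members rose, 4 fell and the camera adjusted p was 0.0771. PFKP, SLC2A1 and KDM3A had 0.75, 0.82 and -2.76 in the planned fit and 0.23, 0.43 and -2.20 after GC correction.

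The integrated stress and unfolded protein response list gave 11 rises, 11 falls and 10 not passed among 32, and 6 rises and 8 falls after GC correction (median GC content 52.3%, camera adjusted p = 0.841). The endoplasmic reticulum chaperones HSP90B1 and DNAJC3 had log2 fold changes of -1.67 and -2.70, SEL1L -2.85 and the cystine transporter SLC7A11 -2.12, which were -0.43, -1.14, -1.25 and -0.29 in the GC-corrected fit. Heat shock genes gave 8 rises, 7 falls and 2 not passed among 17, and 5 rises and 5 falls after GC correction (median GC content 50.2%, camera adjusted p = 0.803). HSPA1A and HSPA1B, whose near-identical sequences make the split of reads between them uncertain, rose from 129 ± 5.14 to 275 ± 6.77 and from 230.2 ± 7.71 to 483 ± 12.7 CPM, and HSPH1 and DNAJB4 had log2 fold changes of -1.81 and -2.19. After GC correction HSPA1A, HSPA1B and HSPH1 had 0.54, 0.54 and -0.34, and DNAJB4, at -0.32, no longer passed (edgeR adjusted p = 0.0549). Cholesterol and fatty acid synthesis gave 17 rises, 10 falls and 4 not passed among 31, and 9 rises and 7 falls after GC correction (median GC content 51.9%, camera adjusted p = 0.445). ELOVL6, STARD4 and IDI1 had log2 fold changes of -2.03, -1.93 and -2.04, of which -0.62, -0.06 and -0.48 were left in the GC-corrected fit, and the desaturase FADS2 had 0.56 and -0.01. STARD4 and FADS2 no longer passed there. Metallothioneins and the zinc exporter SLC30A1 gave 1 rise, 3 falls and 2 not passed among 6 (median GC content 52.2%, camera adjusted p = 0.61). MT2A fell from 4594 ± 86.6 to 3771 ± 241 CPM and MT1X from 472 ± 14.6 to 320.1 ± 17.7 CPM, and both fell in the GC-corrected fit, with log2 fold changes of -0.72 and -0.67. MT1E and SLC30A1 had log2 fold changes of 0.15 and -0.67, and of -0.16 and 1.05 in the GC-corrected fit, where SLC30A1 was the member that rose and MT1E, MT2A and MT1X fell.

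Most of the nuclear genes of oxidative phosphorylation and of cytosolic ribosomal proteins rose, and most transcripts of the mitochondrial genome fell. Of 34 nuclear-encoded subunits of the respiratory chain, 21 rose, 5 fell and 8 did not pass, with a median log2 fold change of 0.28 (median GC content 48%, camera adjusted p = 0.0283, and adjusted p = 0.633 with an estimated correlation). Of all genes in the tenth from 46.8% to 49.8% GC content, 19.6% rose and 35.8% fell. Cytochrome c1, CYC1, rose from 355 ± 17.4 to 659.8 ± 30.8 CPM and UQCRC1 from 156 ± 7.49 to 264 ± 3.57 CPM, and COX8A and COX6A1 had log2 fold changes of 0.56 and 0.49. In the GC-corrected fit 25 rose and 1 fell, CYC1, UQCRC1 and COX6A1 had 0.31, 0.21 and 0.17, COX8A no longer passed at 0.03, and the list had a median of 0.36 and a camera adjusted p of 6.25e-05 (adjusted p = 0.547 with an estimated correlation, and 0.0158 with the GC and length correction). Of 67 ribosomal protein genes, whose reads can be shared with processed pseudogenes, 38 rose, 15 fell and 14 did not pass (median GC content 50.4%, camera adjusted p = 0.0211, and adjusted p = 0.633 with an estimated correlation). Adjusted over the list alone, 38 rose and 16 fell. Of all genes in the tenth from 49.8% to 52.9% GC content, 43.1% rose and 13.8% fell. RPL8, RPS2 and RPL18 had log2 fold changes of 0.91, 0.82 and 0.80, and of 0.32, 0.28 and 0.29 in the GC-corrected fit. There 38 members rose and 13 fell, and the camera adjusted p was 0.00846 (adjusted p = 0.573 with an estimated correlation). With the GC and length correction the list did not pass (camera adjusted p = 0.742).

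Of 13 messenger RNAs of the mitochondrial genome, 10 fell, 2 rose and 1 did not pass, with a median log2 fold change of -0.95 (median GC content 44.3%, camera adjusted p = 0.0283, and adjusted p = 0.648 with an estimated correlation). Adjusted over the list alone, 3 rose and 10 fell. Of all genes in the tenth from 44.1% to 46.8% GC content, 62% fell and 8% rose. MT-CO3 fell from 13753 ± 583 to 6755 ± 396 CPM, MT-CO2 from 10315 ± 831 to 4252 ± 428 CPM and MT-CYB from 4941 ± 277 to 2561 ± 142 CPM, while MT-ND4L, which overlaps MT-ND4, had a log2 fold change of -1.12. Mitochondrial transcripts made up 8.75% ± 0.4 of the counts in control and 4.89% ± 0.19 in ABI2 libraries (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). In the GC-corrected fit 5 members rose and 5 fell, with a median of -0.01 and log2 fold changes of -0.56 for MT-CO3, -0.75 for MT-CO2 and -0.43 for MT-CYB, while MT-ND4L, at -0.01, no longer passed (camera adjusted p = 0.942).

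The list of MYC and ribosome biogenesis gave 15 rises, 11 falls and 3 not passed among 29, and 12 rises and 10 falls after GC correction (median GC content 51.7%, camera adjusted p = 0.584). BOP1, a ribosome assembly factor, and spermidine synthase, SRM, had log2 fold changes of 1.14 and 1.08, and DDX21 and NOP58 had -2.49 and -1.77, which became 0.55, 0.48, -0.96 and -0.37 after GC correction. Proteasome and ubiquitin genes gave 18 rises, 18 falls and 6 not passed among 42 (median GC content 48.5%, camera adjusted p = 0.713), and 20 rises and 18 falls adjusted over the list alone. The GC-corrected fit had 23 rises and 11 falls. The ubiquitin ligase NEDD4 fell from 41.9 ± 5.93 to 3.89 ± 0.22 CPM, the proteasome subunits PSMD8 and PSMD3 had log2 fold changes of 0.85 each, and PSMD12 had -1.56 in the planned and 0.17 in the GC-corrected fit, where NEDD4, PSMD8 and PSMD3 had -1.69, 0.36 and 0.32.

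Most epithelial genes rose and none of those measured fell, and most genes of like GC content rose too. In the tenth of all genes that holds the list's median GC content (59.2% to 62.6%), 72.1% rose and 1.4% fell. Of 17 measured members, 11 rose and 6 did not pass, with a median log2 fold change of 0.71 (median GC content 60.2%, camera adjusted p = 0.00772, and adjusted p = 0.633 with an estimated correlation). The keratins KRT7, KRT8 and KRT80 rose from 40.6 ± 3.32 to 97.7 ± 7.53 CPM, from 206 ± 14.6 to 388 ± 17.2 CPM and from 61.4 ± 2.16 to 124 ± 6.31 CPM, and the protease inhibitor SPINT2 from 135 ± 3.12 to 231 ± 10.4 CPM. After GC correction 8 rose and none fell, with log2 fold changes of 0.68, 0.36, 0.53 and 0.30 for these genes and a camera adjusted p of 0.0792. Mesenchymal and matrix genes gave 19 rises, 12 falls and 7 not passed among 38, and 15 rises and 7 falls after GC correction (median GC content 50.9%, camera adjusted p = 0.325). The urokinase PLAU and its receptor PLAUR rose, with log2 fold changes of 0.996 and 1.04, and of 0.74 and 0.55 in the GC-corrected fit, and the repressor ZEB2 had -1.92 and, no longer passing, -0.28.

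Of 12 luminal breast markers 6 rose, 2 fell and 4 did not pass, and 2 rose and 2 fell after GC correction (median GC content 52.8%, camera adjusted p = 0.325). SPDEF, a luminal transcription factor, rose from 5.3 ± 0.43 to 16.7 ± 1.85 CPM and KRT19 from 26.2 ± 0.99 to 42.3 ± 2.49 CPM, while AGR2 fell from 1.04 ± 0.23 to 0.23 ± 0.11 CPM. After GC correction SPDEF and AGR2 had log2 fold changes of 1.06 and -1.45, and KRT19, at 0.11, no longer passed. Only 4 fibroblast markers passed the filter, too few for camera (median GC content 57.2%). S100A4, COL1A1 and FBLN1 rose, with log2 fold changes of 0.74, 0.35 and 0.36, and COL6A3 had -0.20 ± 0.54 (edgeR adjusted p = 0.759). After GC correction S100A4 and COL6A3 had 0.45 and -0.49, and COL1A1 and FBLN1, at -0.23 and -0.22, no longer passed. Of 5 blood cell markers 2 rose and 3 did not pass, and 1 rose adjusted over the list alone (median GC content 57.3%, camera adjusted p = 0.479). CD68, also made by many cancer lines, rose from 263 ± 1.38 to 404 ± 34.6 CPM and CD14 from 1.16 ± 0.26 to 1.77 ± 0.11 CPM, while CD8A and CSF1R were at 0.82 ± 0.16 and 0.81 ± 0.06 CPM in control and 1.29 ± 0.28 and 0.7 ± 0.08 CPM in ABI2 libraries. After GC correction CD68 and CD14, at 0.20 and 0.09, no longer passed, and CSF1R passed at -0.72 (edgeR adjusted p = 0.0313).

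**Figure D3:**
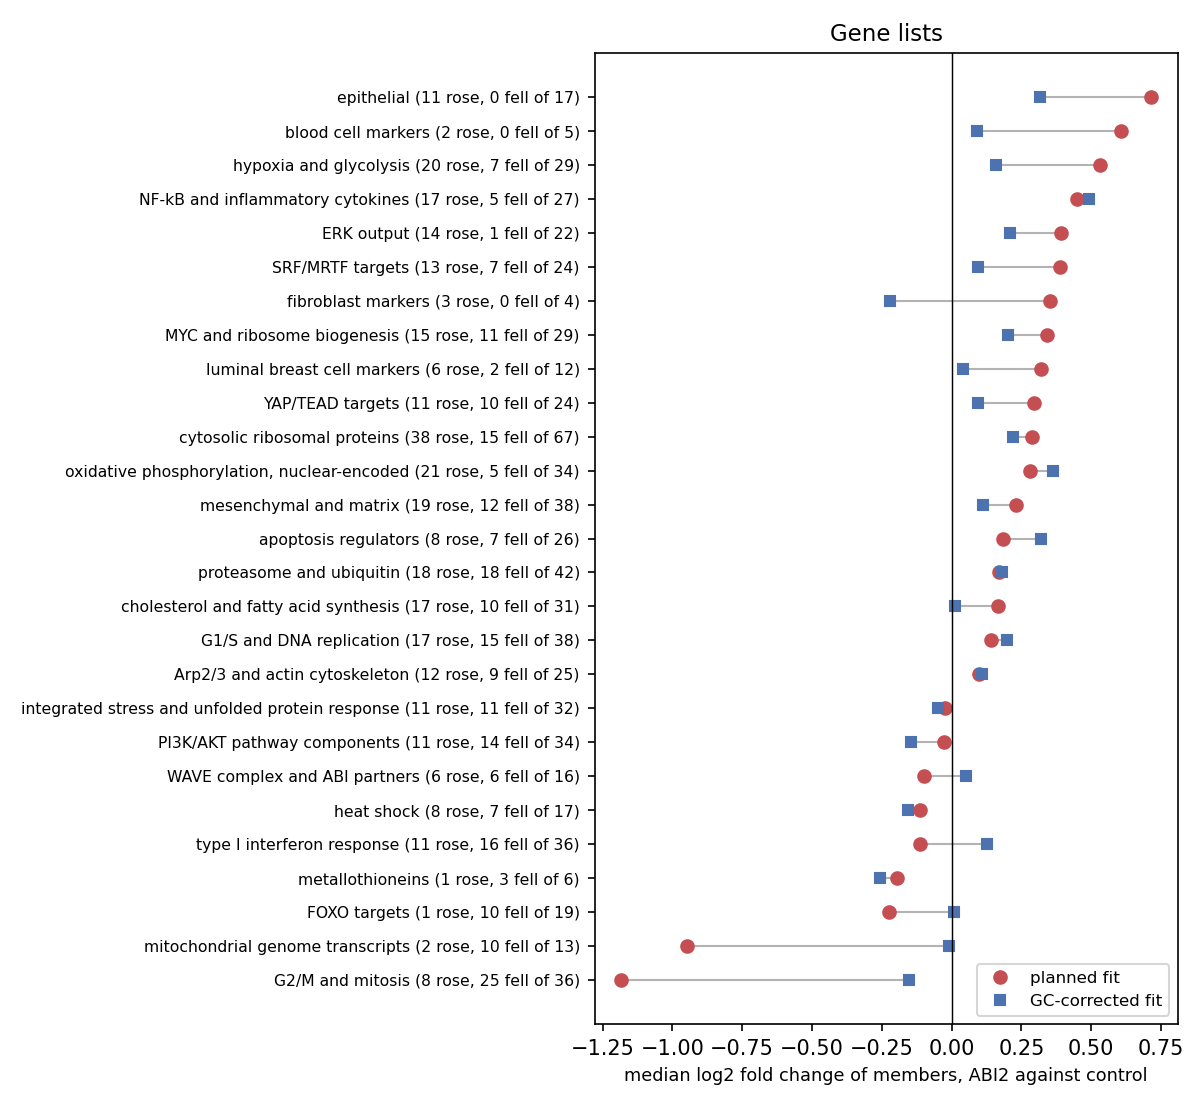
Median log2 fold change of the measured members of each of 27 gene lists, ABI2 against control libraries. Circles are the planned fit, squares the GC-corrected fit, and the counts beside each name are from the planned fit. The G2/M list moved from -1.18 to -0.15, the mitochondrial genome list from -0.95 to -0.01 and the NF-kB list from 0.45 to 0.49.

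**Figure D4:**
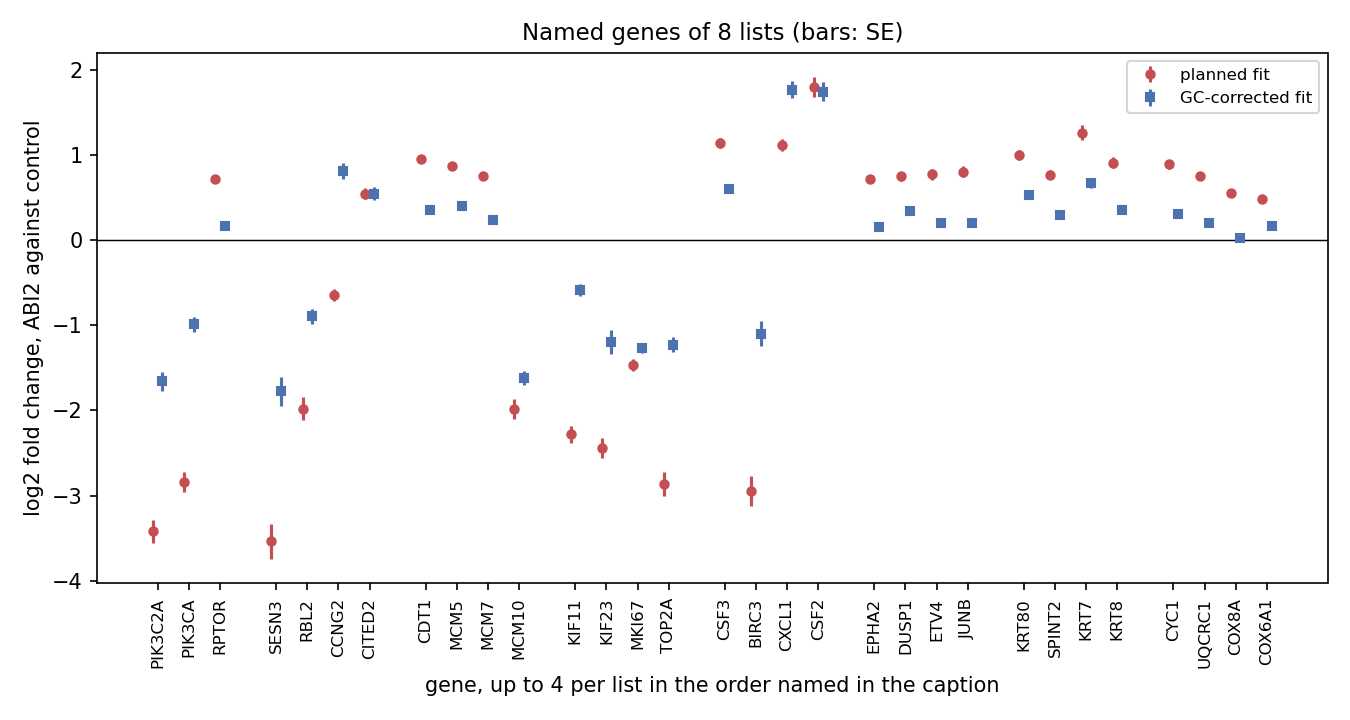
Log2 fold change with its SE for up to 4 named genes in each of 8 lists, in the planned fit (circles) and the GC-corrected fit (squares). From left to right the lists are PI3K/AKT components, FOXO targets, G1/S, G2/M, NF-kB and cytokines, ERK output, epithelial genes and oxidative phosphorylation. CXCL1 was at 1.12 and 1.77, PIK3CA at -2.84 and -0.99 and CCNG2 at -0.64 and 0.81.

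For 22 of the 28 lists the counts of members were the same when adjusted over the list alone, and the other 6 are given above. In 11 lists the mean log2 fold change had the opposite sign of the camera direction, and in 2 of these, heat shock and the integrated stress response, the median did too. The others reported here were the lists of Arp2/3 and actin, G1/S, cholesterol synthesis, mesenchymal genes, YAP/TEAD targets, MYC, proteasome and apoptosis, in which falls were larger than rises. Camera compares a list with all other genes, so its direction is relative to them. A list with a negative mean can therefore be placed up.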

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

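The test of the plasmid transcript was chosen after the result was seen. The deposited TPM values held a larger ABI2 difference than the counts did. ABI2 was at 16.7 ± 1.68 TPM in control and 134 ± 36.8 TPM in ABI2 libraries (SD, n = 3 each), an 8.04-fold difference, against 2.69-fold in CPM. The length implied by counts and FPKM went from 10174 ± 732 bp to 3264 ± 752 bp (exact permutation p = 0.1, the smallest possible). Reads from a plasmid transcript without the native untranslated regions stay open as an explanation. The ratio of implied lengths, 0.32, lay at percentile 0.03 of 10551 expressed genes, but it is computed from the same counts and FPKM and restates the difference, so it does not test this. Loss of reads from long 3' untranslated regions of low-GC transcripts, as the whole cause, was argued against by 304 other genes. These had such a region of at least 5000 bp and a low GC content of the whole transcript. Their median ratio was 1.003, and none had a ratio as low as that of ABI2. The lowest 5% of their ratios reached up to 0.662, whereas the central 95% of all expressed genes began at 0.797. Low ratios were thus more common among these genes, and such a loss as a part of the ABI2 difference stays open. The GC content of the region itself was not used to choose the 304 genes. How many had a region as long as that of ABI2, 20374 bp, was not examined.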

How the results depend on the processing

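The GC and the GC and length corrections, library size without TMM and the TPM fit were chosen after seeing the data; the planned settings for tables without counts (pseudocount, filters, centring and moderation of normalized values) were not run because the table holds counts. The count of 9737 changed genes lay between 8545 and 9863 under the other fits except the GC correction (6820), the GC and length correction (6675) and the minimum log2 fold change of 1 (3569). Without 1 library it ranged from 9082 to 9574, with 4369 to 4562 genes higher and 4713 to 5012 lower. With the minimum fold change, 247 were higher and 3322 lower. With the GC correction 3009 were lower, and with GC and length 2937, where 3738 were higher. GC and length kept 4149 of the planned calls in direction and called 1246 in the opposite one. The replicate numbers gave no pairing (correlations of the deviations 0.022, 0.019 and 0.061), and with the number as a replicate block 9477 genes changed, ABI2 had 1.43 and 8 lists passed. The log2 fold change of ABI2 was between 1.33 and 1.45 (ABI2 level without TMM 1.33, RLE 1.45) in the other count fits, 2.78 with the GC correction, 3.19 with GC and length and 2.91 with TPM, and 1.43 to 1.44 without 1 library. The values of ABI2 with the GC and the GC and length corrections rest on the annotated transcript, which a plasmid transcript need not match. Of 27 lists 8 passed with camera, 7 or 8 without 1 library, 3 with the GC correction (NF-kB, oxidative phosphorylation, ribosomal proteins), 3 with GC and length (NF-kB, oxidative phosphorylation, G2/M), 4 with TPM, 0 with an estimated correlation, 0 with the GC correction and an estimated correlation, and 23 with fry, which does not compare a list with other genes. For the integrated stress list fry gave the opposite direction (adjusted p = 0.00666).

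Of the 144 named genes besides ABI2 with a GC value, 10 that passed in the planned or the corrected fit changed sign with the GC correction and 14 others lost their call; with the GC and length correction these were 13 and 21. With the GC correction and then with GC and length, the log2 fold changes were 1.26 and 1.19 for ABI1, 0.81 and 0.94 for CCNG2, 0.28 and 0.22 for BNIP3L, 0.17 and 0.18 for PSMD12, 1.05 and 1.15 for SLC30A1, -0.16 and -0.36 for MT1E, -0.22 and -0.28 for FBLN1, and 0.60 and 0.76 for SMAD9. With the GC correction alone FADS2 had -0.0123 and COL1A1 -0.23, and with the GC and length correction the log2 fold change of CFL1 was -0.0123, of COX8A -0.11, of COX6A1 -0.0045, of KRT19 -0.0304 and of CD14 -0.0299. Both fits measure a gene against others of its GC content. No such change of sign was seen under the settings fixed beforehand; at most 5 lost their call without 1 library, and 57 lay below the minimum fold change. With totals of 38.45 to 40.31 in units of 1e6 counts, the SE of log2 fold changes near 1 CPM were 0.26 for CD8A, 0.54 for COL6A3 and 0.22 for CSF1R, and spread between libraries gave as large an SE at higher levels, 0.56 for SH3BP1.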

Other observations

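Of the tests below, those of RNA length, of the mitochondrial transcripts and of GC-matched G2/M lists were chosen after the result was seen, as were the GC corrections and the genes of the first 2 paragraphs. SMAD6, an inhibitor of BMP signalling, rose from 7.06 ± 0.63 to 16.1 ± 1.21 CPM and ATOH8 from 3.35 ± 0.52 to 6.94 ± 0.79 CPM (SD, n = 3 each), beside ID1 and ID3. SMAD6 and ATOH8 had log2 fold changes of 0.65 and 0.45 in the GC-corrected fit. SMAD7 and BAMBI had log2 fold changes of 0.79 and 0.50, which lost their call with the GC correction at 0.26 and 0.15. ID2 and ID4 had 0.38 ± 0.28 and -0.19 ± 0.29 (SE), did not pass, and had 0.08 and 0.22 in the GC-corrected fit, and SMAD9 had -0.45 and 0.60 in the planned and GC-corrected fits.

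OASL, an interferon-induced antiviral protein, rose from 21.3 ± 2.75 to 69.5 ± 4.53 CPM, the RNA helicase DHX58 from 4.61 ± 0.09 to 13.1 ± 1.22 CPM and the adaptor MYD88 from 18.2 ± 3.11 to 61.6 ± 19 CPM. After GC correction their log2 fold changes were 1.55, 0.98 and 1.47. FOXO3 fell from 87.3 ± 0.31 to 48.4 ± 2.24 CPM, with log2 fold changes of -0.85 and -0.76 in the planned and GC-corrected fits, and FOXO1 had -0.80 and, no longer passing, -0.30.

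The fold changes rose with transcript GC content, with Spearman's rho of 0.777 in the lower and 0.793 in the upper part of the genes by mean expression. A GC bias of library preparation that differed between the groups is a candidate explanation. Within ribosomal proteins, respiratory chain subunits and proteasome genes, centred on each list, rho was 0.738 over 143 members. The permutation p was 1e-05, the smallest that 100000 permutations can give, but it shuffles genes and not libraries. Over all genes rho was already 0.79, so a high rho within these lists was likely whatever the cause. GC-dependent RNA stability would give the same, so this test does not single out library preparation. Loss of long transcripts as the whole cause was argued against by a rho of at least 0.663 in each quartile of length, a test written after the first one, the partial rho of length given GC, gave -0.213 and met neither of its bounds. An effect on low-GC nuclear transcripts alone was argued against by the median of -0.948 (95% bootstrap interval -1.12 to -0.61) of the 13 mitochondrial transcripts. That interval resamples transcripts and not libraries, so it does not measure the spread between samples. The median does not speak against an effect on low-GC nuclear transcripts beside a change of mitochondrial RNA. The trend splits the libraries as the plasmid does, so a biological effect of ABI2 on GC-rich and GC-poor transcripts stays open, and of the 10 splits of the 6 libraries, too few for a share under 0.05, the real 1 gave 9737 changed genes and the highest of the others 0.

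The G2/M genes fell with a median of -1.18, and lists of equal GC content drawn at random had a median of -0.63. After the GC correction the median was -0.15, at percentile 3.28 of 10000 random lists, just inside their central 95% (-0.166 to 0.215), with a bootstrap interval of -0.64 to 0.05. That met the bound set beforehand for GC content as the whole cause, whereas in the GC-matched comparison of the planned fit, added later, the list lay at percentile 1.06. The correction for GC and length gave a camera adjusted p of 0.00998, against 0.0771 with GC alone, while with an estimated correlation it was 0.633 in the planned fit and 0.573 with GC alone. For fewer mitotic cells in the ABI2 libraries, the bounds set beforehand were a corrected median below the 2.5th percentile of the random lists and at least 80% of members below 0. The corrected median, above -0.166, and the 58.3% of members below 0 missed both. A median above that percentile was also the bound set beforehand against fewer mitotic cells, and it was met. By those bounds fewer mitotic cells was argued against, but the GC-matched comparison added later lay on the other side. The random lists and the bootstrap draw genes and not libraries, so neither measures the spread between samples. Genes drawn at random also need not vary together as members of a list can. Because the median's bootstrap interval also spans -0.166, GC content as the whole cause and a lower share of mitotic cells cannot be told apart here.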
